A study of Homo sapiens with 14 samples.

How the data were processed

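RNA of human H1299 cells was measured on 14 arrays, in 7 groups of 2 taken from the labels: wild-type cells with siNT, sip300 or siCBP, CBPKO cells with siNT or sip300, and p300KO cells with siNT or siCBP, all at 48 h. Per the labels' protocols, siRNAs were delivered with a lipid reagent, total RNA was purified on columns, and Cy3-labelled cRNA was hybridised in 1 colour. Per the file headers, each deposited array file holds spot intensity values from Agilent Feature Extraction 10.7.3.1, whose processed signal is background-subtracted and spatially detrended, with no scaling between arrays. The same files give raw median intensity of spot and local background, per the file headers, along with deposited flags for spots well above background, saturated or outlying. The submitters' processing notes name Agilent Feature Extraction. The file of wild-type siNT replicate 1 carries its values at 3 significant digits. The deposited table of the whole series holds intensity values that equal the processed signal of the same spot rounded to 3 significant digits: their scale is linear, and no centring or direction applies. Its column medians ran from 59.7 to 85.1, and it served as an alternative source.

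The processed signal of 58717 non-control spots was put on the log2 scale and reduced by each array's 75th percentile. Spots with an outlier flag were left out, spots of one probe were averaged, and 14 probes with no value left on an array were dropped. A probe was tested where it lay well above background on every array of at least 1 group (29480 of 42405 probes). Of a gene's probes the one with the highest mean over all arrays stood for it, which gave 24646 tested genes or transcripts, 14733 of them with a symbol; 137 genes had probes called in opposite directions for sip300 in CBPKO cells. The files used here carry an accession per probe and no symbol. Of 25863 probes with a RefSeq accession, 24910 (19102 symbols) were named through a table of RefSeq genes of assembly GRCh38.p14, and 17495 probes stayed unnamed and were counted but not named in the text. The design of the arrays was annotated on hg19 per the file headers, so coordinates of that table are not given; it was used for names and for which genes neighbour each other.

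Differences were tested with limma 3.58.1 (R 4.3.3) on all 14 arrays with a mean per group, empirical Bayes moderation (7 residual and 2.42 prior degrees of freedom, median residual SD 0.126) and Benjamini-Hochberg adjustment per comparison, called at an adjusted p under 0.05. The 11 comparisons were each knockdown against siNT in its line, the differences of these effects between lines, sip300 against siCBP in wild-type cells, and the lines against each other under siNT. Before the data were examined, the design, the alternatives, the rule for named genes and 30 gene lists with 581 members (573 on the array, 17 of them under an older symbol) were fixed. The lists were tested with camera at a preset correlation of 0.01 where 5 or more members were tested, adjusted over the 30 lists, and again with a correlation estimated per list. The named genes are CREBBP, EP300 and MYC, the 8 largest rises and falls (5 in other comparisons) among called genes whose arrays do not overlap between groups, up to 4 called members with the lowest p of each list that passes camera, and up to 2 of other lists. One restriction was added after the data were seen: a gene ranked by size had to be well above background on at least 1 array of each group compared. A gene not well above background in one of the groups compared is given as "at least N-fold", and where no such bound can be formed its value is marked as resting on signals not well above background. The bound comes from the mean of the brighter group against the mean over arrays of the higher of the lowest signal well above background and the gene's own signal. That lowest signal is taken over all probes of an array. A single probe's limit can lie higher, so the bound is approximate. The ± values are standard errors of limma's log2 difference with 2 arrays per group.

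The steps were tested on simulated data built from each gene's mean over all arrays and its moderated spread, over 24646 genes. For sip300 in CBPKO cells, 28 of 80 genes changed by 0.5 on the log2 scale were recovered (35.0%), 64 of 80 changed by 1 (80.0%) and 38 of 40 changed by 2 (95.0%), with 5 false calls. For the difference of the sip300 effects, 5 of 80 (6.25%), 40 of 80 (50.0%) and 34 of 40 (85.0%) were recovered, with 5 false calls. A list of 20 genes shifted by 0.5 was called, and of 20 lists with no shift 0 were called. Simulated genes varied independently, so the list result does not cover lists of correlated genes. Far fewer genes were changed than were called in the data, so the shares recovered need not hold there. The alternatives were quantile normalization, normexp background correction (offset 50, on the spot median because the files used here hold no spot mean), no filter or a stricter filter on dim probes, the mean of a gene's probes, trended and robust moderation, the replicate number as a block, the arrays of the same slide or of the compared groups alone, the deposited table, each array left out in turn and, added after the data were seen, centring on the median. Slide as a term in the model is absorbed by the groups, since each group lay on 1 of 2 slides. Groups of 2 are too small for other splits of the samples and for a test of single outlying arrays. The simulation of shared controls drew 20 sets of unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with pandas 2.3.3.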

Results

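RNA levels were measured in H1299, an established line from a human lung carcinoma, on 14 Agilent arrays that each took RNA from 1 sample in 1 colour. CBP and p300, the products of CREBBP and EP300, are closely related lysine acetyltransferases that act as coactivators of many transcription factors. The samples form 7 groups of 2 arrays, all taken 48 h after transfection of an siRNA. Wild-type cells received siNT (the control siRNA), sip300 or siCBP, cells labelled as lacking CBP (CBPKO) received siNT or sip300, and cells labelled as lacking p300 (p300KO) received siNT or siCBP. The title of the series places the work in the search for expression signatures of synthetic lethal genes, that is, genes whose loss harms cells that already lack a partner gene. The 75th percentile of the processed signal ran from 547 to 889 per array, 63.6% to 70.0% of the spots lay well above background, and 0 spots were saturated. The arrays of a group correlated at r = 0.993 or more across probes, and the most similar arrays of different groups at r = 0.994; probes are not independent replicates. Of the variance between arrays, 45.8%, 26% and 14.8% lay on the first components. The series text gives 2 independent experiments, so the p-values measure the spread between samples. With 2 arrays per group, the precision of each value is limited.

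The targeted genes were examined first. CREBBP fell under siCBP by 1.24 on the log2 scale in wild-type cells (SE 0.088, n = 2 arrays per group), which left 42.3% of the wild-type siNT level. In p300KO cells it fell by 1.5 (SE 0.088), from 127% of that wild-type siNT level under siNT to 45.0% of it under siCBP. CBPKO cells held 54.7% of the wild-type CREBBP signal under siNT and 102% under sip300, a rise of 0.90 ± 0.088. The EP300 probe was dim: it lay well above background on both arrays in wild-type siCBP and CBPKO siNT cells, on 1 array in wild-type siNT cells and on 0 arrays in the other 4 groups. Under sip300, EP300 was at least 4.04-fold lower in CBPKO cells (adjusted p = 3.94e-06) and at least 1.81-fold lower in wild-type cells (adjusted p = 0.000163). In p300KO cells under siNT it was at least 1.67-fold lower than in wild-type cells, of whose arrays 1 measured it. Against CBPKO cells it was at least 3.03-fold lower. Both EP300 signals in wild-type siNT cells (-4.7 and -4.37) exceeded the lowest signal well above background on their arrays (-4.89 and -5.37), yet only 1 counted. These bounds are therefore approximate. Where these probes lie relative to the edits of the knockout lines is not known here, so the signals in those lines do not check the labels.

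MYC, which encodes a transcription factor that drives growth and ribosome production, was fixed as a gene of interest along with both targets. It fell 4.4-fold under sip300 in CBPKO cells (log2 change -2.14 ± 0.067, SE, n = 2 arrays per group) and 2.53-fold under siCBP in p300KO cells (-1.34 ± 0.067). In wild-type cells the sip300 difference did not pass the test (-0.22 ± 0.067, adjusted p = 0.0733), and siCBP raised MYC by 0.37 ± 0.067. Relative to wild-type cells under siNT, MYC signal stood at 143% in CBPKO siNT, 32.6% in CBPKO sip300, 91.8% in p300KO siNT and 36.3% in p300KO siCBP cells. The test of the difference between lines gave -1.91 ± 0.095 for sip300 (adjusted p = 1.89e-06) and -1.71 ± 0.095 for siCBP (adjusted p = 3.49e-06).

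**Figure D1:**
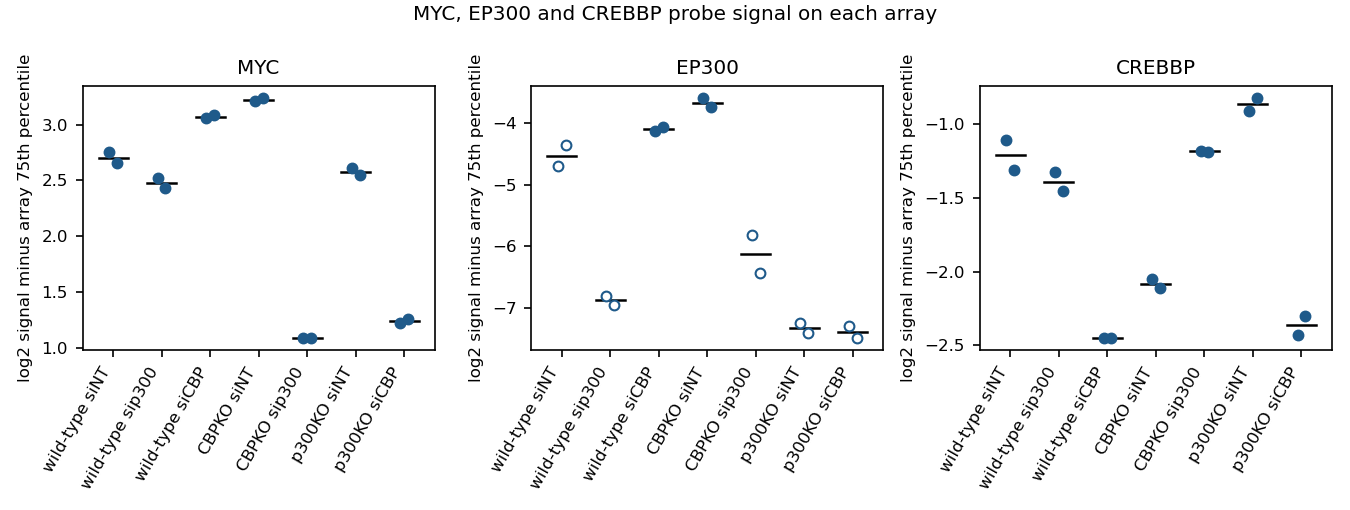
Probe signal (log2 minus the array's 75th percentile) of MYC, EP300 and CREBBP on each of the 14 arrays; each circle is 1 array, the bar is the mean of 2 arrays, and open circles mark groups in which the probe was not well above background on both arrays. MYC means are 3.22 in CBPKO siNT and 1.09 in CBPKO sip300, and 2.58 in p300KO siNT and 1.24 in p300KO siCBP cells.

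Treatment of CBPKO cells with sip300, the comparison the title points to, was followed by broad change. Among genes well above background on at least 1 array of each group, the largest rises were those of CCN2, which encodes connective tissue growth factor (45.4-fold higher, log2 change 5.51 ± 0.089), and of EGR1, an immediate early transcription factor (5.03 ± 0.085). NR4A3, an orphan nuclear receptor (3.94 ± 0.15), EGR4 (3.67 ± 0.78), CLIP3 (3.50 ± 0.091), TM7SF2, a sterol reductase (3.49 ± 0.097), LYRM9 (3.42 ± 0.17) and DOK4, a docking protein of tyrosine kinases (3.21 ± 0.10), followed. The largest falls among the same genes were in TGFBI, an extracellular matrix protein induced by TGF-beta (57.9-fold lower, -5.86 ± 0.074), CCL2, a chemokine that attracts monocytes (-5.69 ± 0.099), UCN2, a peptide hormone of the urocortin family (-5.65 ± 0.12), and DMBT1 (-5.25 ± 0.12). ASB2, well above background on 1 array of a group (-4.69 ± 0.11), TMEM158 (-4.55 ± 0.091), DEPP1 (-4.53 ± 0.20) and the adhesion receptor gene ADGRG1 (-4.22 ± 0.11) also fell. For each of these genes the 2 sip300 arrays lay on one side of the 2 siNT arrays.

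Genes of the cell division cycle fell together in CBPKO cells under sip300. Of 26 tested genes of E2F targets and DNA replication, 25 fell and 1 rose (median -2.08, camera adjusted p = 1.3e-12), among them CDC45 (-2.82 ± 0.064) and MCM7 (-2.40 ± 0.071) of the replicative helicase, the licensing factor CDT1 (-2.47 ± 0.072) and E2F1 itself (-2.14 ± 0.064). All 25 tested genes of G2/M and mitosis fell (median -1.52, adjusted p = 1.93e-11, adjusted p = 0.0811 with an estimated correlation). Among these were cyclin A2 (CCNA2, -2.90 ± 0.092), CDC20 (-2.02 ± 0.066), which activates the anaphase-promoting complex, the centromeric histone CENPA (-2.11 ± 0.075) and Aurora kinase B (AURKB, -2.40 ± 0.094). Of 20 DNA repair genes, 16 fell and 1 rose (median -1.24, adjusted p = 1.95e-05, adjusted p = 0.103 with an estimated correlation). Among these were RAD54L (-3.11 ± 0.087) and XRCC2 (-2.27 ± 0.09), both of homologous recombination, and the exonuclease EXO1 (-1.94 ± 0.075). Among 30 MYC targets, 29 fell and 0 rose (median -1.06, adjusted p = 9.33e-11), such as E2F2 (-2.70 ± 0.082) and the nucleolar factors MRTO4 (-1.98 ± 0.068), RRS1 (-1.68 ± 0.066) and NOP56 (-1.73 ± 0.068). Ribosome biogenesis genes fell in 19 of 20 cases and rose in 1 (median -0.76, adjusted p = 2.85e-05, adjusted p = 0.121 with an estimated correlation). Among these were BRIX1 (-1.14 ± 0.066), EBNA1BP2 (-1.17 ± 0.073) and RRP9 (-1.16 ± 0.073). UTP15 fell furthest (-2.79 ± 0.14), and it also fell under sip300 in wild-type cells (-1.57). These counts were the same adjusted over the list alone.

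Other gene groups rose in the same comparison. Of 20 autophagy and lysosome genes, 15 rose (16 adjusted over the list alone) and 1 fell. They include the autophagosome gene GABARAPL1 (1.99 ± 0.08), the lysosomal sialidase NEU1 (2.09 ± 0.11) and WIPI1 (1.60 ± 0.084). The list's median was 0.83 (adjusted p = 2.34e-07, adjusted p = 0.119 with an estimated correlation). Interferon response genes rose in 12 of 18 cases, 12 adjusted over the list alone, and fell in 0 (median 0.40, adjusted p = 0.000347). IFIT2 (1.82 ± 0.12) and IRF9 (1.66 ± 0.13) were among them, and IFIT3 was at least 3.34-fold higher than in CBPKO siNT cells, where it was not well above background. HDACs and bromodomain readers rose in 14 of 20 cases and fell in 1 (adjusted p = 0.000114, adjusted p = 0.121 with an estimated correlation). Among these were the sirtuin genes SIRT2 (1.10), SIRT1 (0.78) and SIRT3 (0.69). Targets of YAP and TEAD split 9 higher to 3 lower of 15 (adjusted p = 0.00873, adjusted p = 0.0811 with an estimated correlation), with CCN2 and LATS2 (1.70) higher and AXL (-1.60) and NUAK2 (-1.53) lower. Lysine acetyltransferases split 11 to 4 of 18 (adjusted p = 0.00934, adjusted p = 0.269 with an estimated correlation), with KAT2B (1.80) and NCOA1 (1.67) higher and KAT2A (-1.49) lower. Targets of p53 split 11 to 6 of 19 (adjusted p = 0.019, adjusted p = 0.119 with an estimated correlation), with TP53I3 (1.5) and the cyclin-dependent kinase inhibitor CDKN1A (1.45) higher and DDB2 (-1.31) lower. SWI/SNF subunits split 8 to 3 of 17 (adjusted p = 0.0368, 0.0648 under quantile normalization, adjusted p = 0.269 with an estimated correlation), with SMARCE1 (0.68) and SMARCC2 (0.62) higher and ACTL6A (-0.92) lower. Adjusted over the list alone, these splits did not change.

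TGF-beta and SMAD targets fell in 11 of 15 cases and rose in 2, the same adjusted over the list alone (median -0.80, adjusted p = 0.00453, adjusted p = 0.0811 with an estimated correlation). Among these were TGFBI and the inhibitors of differentiation ID1 (-1.98 ± 0.081) and ID2 (-1.59 ± 0.078). Cholesterol and fatty acid synthesis genes fell in 14 of 23 cases and rose in 2, also the same adjusted over the list alone (adjusted p = 0.0118, 0.105 after normexp, adjusted p = 0.411 with an estimated correlation). Among these were INSIG1 (-2.31), SREBF1 (-1.5) and FDPS (-1.34). Ribosomal protein genes were lower in 17 of 18 cases, 18 adjusted over the list alone (median -0.36, adjusted p = 0.00811, adjusted p = 0.541 with an estimated correlation), a direction that turned under quantile normalization (median 0.03, adjusted p = 0.616). Outside these lists, the initiator caspase gene CASP9 rose (2.50 ± 0.075), while DKK1 (-4.11), cyclin D1 (CCND1, -2.18), VEGFA (-2.22), FOSL1 (-2.31) and BIRC3 (-1.84) fell. The other 15 lists did not pass camera (adjusted p of 0.138 or more). The split of higher to lower members was 11 to 11 for the BCL2 family and apoptosis, 9 to 8 for AP-1 and immediate early genes, 10 to 8 for ATF4 and the unfolded protein response, 8 to 7 for HIF targets and 5 to 8 for NF-kB targets. It was 2 to 4 (2 to 5 adjusted over the list alone) for WNT targets, 1 to 6 for EMT factors, 2 to 7 for epithelial markers, 5 to 5 for extracellular matrix, 3 to 7 for replication-dependent histones, 3 to 5 for glycolysis and 7 to 10 for heat shock and oxidative stress. Markers of neuroendocrine cells split 6 to 3, of alveolar and airway cells 0 to 5 and of immune and endothelial cells 1 to 3; the splits of these lists, WNT targets aside, did not change adjusted over the list alone.

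In all, 15067 of 24646 tested genes or transcripts changed in this comparison (limma, Benjamini-Hochberg adjusted p under 0.05), 5727 higher and 9340 lower, 3815 of them by more than 2-fold, and 13911 passed in a fit within the slide. The median of all genes moved by -0.20 under the 75th percentile scaling and by -0.04 under quantile normalization, which called 6801 higher and 6791 lower; centring on the median called 6401 and 7715, and normexp 4993 and 13169. Changes smaller than that shift have no settled direction. Of the 30 lists, camera called 15, and 3 of these (E2F targets, MYC targets and the interferon response, each at adjusted p = 0.0499) held with an estimated correlation.

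**Figure D2:**
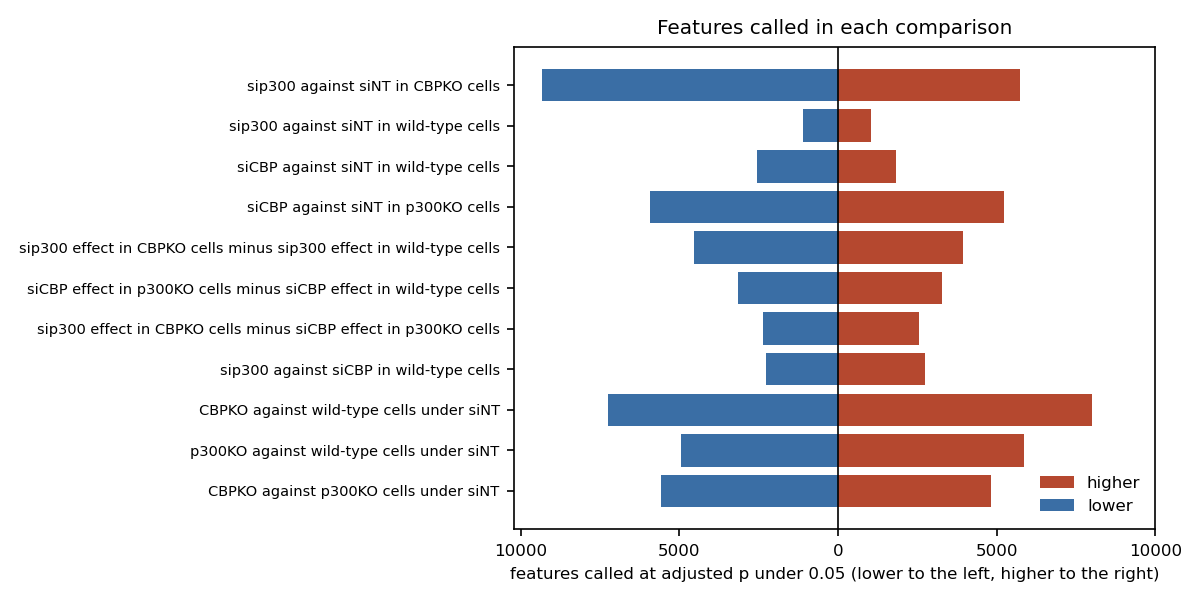
Number of features called at adjusted p under 0.05 (limma, 7 groups of 2 arrays) in each of the 11 comparisons, with lower calls drawn to the left and higher calls to the right of 0. The bars for sip300 in CBPKO cells reach 5727 higher and 9340 lower, and those for sip300 in wild-type cells 1036 and 1091.

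Treatment of p300KO cells with siCBP asked the reciprocal question, with genes ranked in the same way. CCN2 (34.3-fold higher, 5.10 ± 0.089), NR4A3 (4.83 ± 0.15), EGR1 (4.74 ± 0.085) and EGR4 (well above background on 1 array of a group, 4.40 ± 0.78) again led the rises. The coagulation inhibitor TFPI2 (4.16 ± 0.14), FOS (3.72 ± 0.14), NR4A2 (3.61 ± 0.11) and the metalloproteinase inhibitor TIMP1 (3.56 ± 0.076) came next. The pattern recognition gene PTX3 fell 34.6-fold (-5.11 ± 0.10), as did TMEM158 (-4.87 ± 0.091), TGFBI (-4.16 ± 0.074), the kinetochore gene SKA3 (-4.51 ± 0.12) and DEPDC1 (-4.10 ± 0.15). The histone genes H1-5 (-5.49 ± 0.28) and H3C15 (-5.06 ± 0.23) and the acute phase gene SAA1, well above background on 1 array of a group (-4.21 ± 0.14), are uncertain because near-identical copies exist.

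All 25 tested genes of G2/M and mitosis fell under siCBP in p300KO cells (median -2.80, adjusted p = 1.61e-20, adjusted p = 0.0508 with an estimated correlation). Among these were CCNA2 (-3.59 ± 0.092), CENPA (-3.50 ± 0.075), CDC20 (-3.09 ± 0.066) and the mitotic kinase CDK1 (-2.80 ± 0.069). Of 26 E2F and replication genes, 25 fell and 1 rose (median -2.24, adjusted p = 1.37e-17), with CDC45 (-3.21 ± 0.064), CDT1 (-3.01 ± 0.072), MCM6 (-2.93 ± 0.073) and thymidine kinase TK1 (-2.83 ± 0.068). DNA repair genes fell in 16 of 20 cases (median -1.86, adjusted p = 9.51e-09, adjusted p = 0.0723 with an estimated correlation). Among these were RAD54L (-3.52) and FANCI (-2.12). MYC targets fell in 24 of 30 cases (median -0.58, adjusted p = 9.38e-08, adjusted p = 0.0927 with an estimated correlation). Among these were E2F2 (-3.02), the telomerase gene TERT (-2.23) and MRTO4 (-1.41). Autophagy and lysosome genes rose in 18 of 20 cases, 19 adjusted over the list alone (median 0.91, adjusted p = 2.98e-10, adjusted p = 0.101 with an estimated correlation). Among these were NEU1 (2.22), GABARAPL1 (1.70) and the cathepsin gene CTSB (1.48). HDACs and bromodomain readers split 12 to 1 of 20 (12 to 2 adjusted over the list alone, adjusted p = 0.00344, adjusted p = 0.238 with an estimated correlation), with SIRT1 (1.18) and SIRT2 (1.27) higher. AP-1 and immediate early genes split 12 to 6 of 19 (12 to 7 adjusted over the list alone, adjusted p = 0.0214, adjusted p = 0.238 with an estimated correlation), with FOS and JUN (2.43) higher and FOSL1 (-1.95) lower. The counts for the first 4 of these lists were the same adjusted over the list alone.

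Several lists that passed in CBPKO cells did not pass here. Interferon response genes split 8 to 1 (adjusted p = 0.0603, 0.0471 after normexp), p53 targets 10 to 5 (adjusted p = 0.0665), with CDKN1A at 2.50 ± 0.097, and ribosome biogenesis 2 to 11 (adjusted p = 0.0665, 0.0369 under quantile normalization). TGF-beta targets split 5 to 7 (adjusted p = 0.65), and these 4 splits did not change adjusted over the list alone. CTH (3.31 ± 0.094) and ATF3 (3.09 ± 0.096) rose within a list of ATF4 and unfolded protein response genes that split 11 higher to 7 lower and did not pass (adjusted p = 0.0727, adjusted p = 0.491 with an estimated correlation). ICAM1 (2.72 ± 0.098) and CXCL1 (2.61 ± 0.14) rose against the direction of most NF-kB and inflammatory targets, which split 4 to 9 (median -0.51, adjusted p = 0.31); both splits were the same adjusted over the list alone. CASP9 rose by 1.00 ± 0.075. In total 11167 of 24646 features passed limma's test, 5227 higher and 5940 lower, 2924 by more than 2-fold, and 10161 passed within the slide. Under quantile normalization 5883 were higher and 5298 lower. Camera called 7 of the 30 lists, and 1 of these, E2F and DNA replication (adjusted p = 0.0409), held with an estimated correlation.

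**Figure D3:**
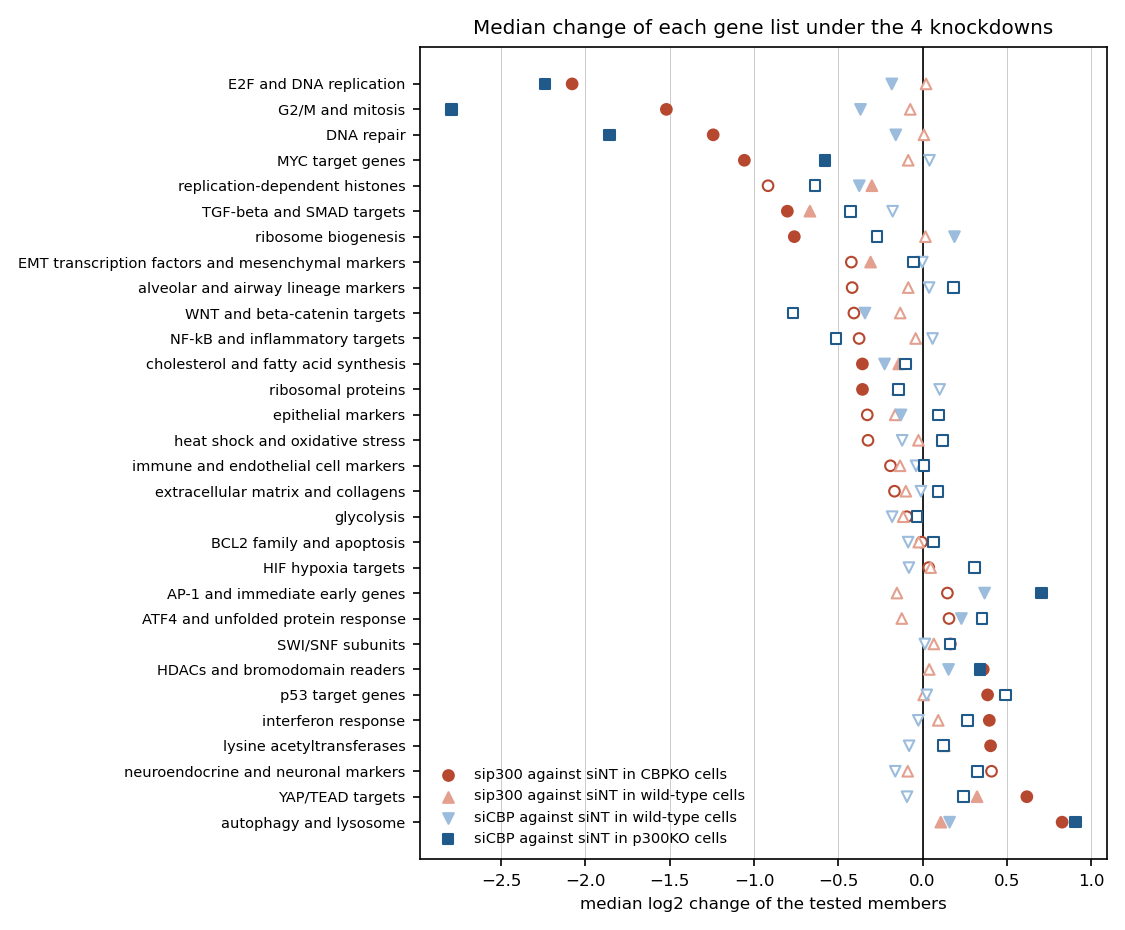
Median log2 change (x axis) of the tested members of each of the 30 gene lists under the 4 knockdowns, 1 symbol per knockdown and list, filled where camera with a preset correlation gave an adjusted p under 0.05. E2F and DNA replication sits at -2.08 for sip300 in CBPKO cells and -2.24 for siCBP in p300KO cells, and at 0.02 and -0.18 for the same siRNAs in wild-type cells.

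The responses of CBPKO cells to sip300 and of p300KO cells to siCBP were then set side by side. Of the genes called in both, 3874 were higher in both and 4347 lower in both, against 1215 and 2251 if the calls were independent, and the log2 changes correlated at r = 0.693 (Spearman's rho 0.668) across 24646 genes, which are not independent replicates. Among genes well above background on at least 1 array of each group, CCN2, EGR1 and NR4A3 stood in the 8 largest rises, and TGFBI and TMEM158 in the 8 largest falls, of each. The direct test of the difference called 4889 features, 2536 with the higher change under sip300 in CBPKO cells and 2353 with the lower. The glucose transporter gene SLC2A3 (4.03 ± 0.17), GNE (2.87 ± 0.11), PTX3 (2.79 ± 0.15), TMCO1 (2.73 ± 0.11) and SRSF12, well above background on 1 array of a group (2.79 ± 0.41), had the higher change in CBPKO cells. PXK (-3.26 ± 0.18), TM4SF1 (-3.21 ± 0.098), GFPT2 (-2.94 ± 0.15), UTP15 (-2.93 ± 0.19) and CALB2, well above background on 1 array of a group (-3.10 ± 0.32), had the lower change there. GFPT2 aside, these genes also fell under sip300 in wild-type cells (PXK -1.5, TM4SF1 -1.24, UTP15 -1.57, CALB2 -1.31). For such genes the contrast cannot separate a general sip300 effect from a difference between the lines. CALB2 also started far higher in CBPKO than in p300KO cells under siNT (below), so its lower change cannot be told apart from that unequal start. GFPT2 started far higher in CBPKO than in wild-type cells (below), so its response in wild-type cells does not settle the question for it. MYC fell further in CBPKO cells (-0.80 ± 0.095), and 16 of its 30 targets did so too against 1 the other way (21 and 2 adjusted over the list alone, adjusted p = 9.72e-06, adjusted p = 0.146 with an estimated correlation). G2/M genes fell further in p300KO cells in 22 of 25 cases, 23 adjusted over the list alone (median difference 1.06, adjusted p = 3.72e-20, adjusted p = 0.0546 with an estimated correlation), as HMMR (1.72) and KIF20A (1.94) show. TGF-beta targets were lower in the CBPKO response in 8 of 15 cases and higher in 2 (11 and 2 adjusted over the list alone, median -1.48, adjusted p = 0.000224, adjusted p = 0.0546 with an estimated correlation). Among these were ID2 (-2.58) and ID1 (-1.48). TGF-beta targets also fell as a list under sip300 in wild-type cells (below), so the same limit holds for them. Quantile normalization split the differences 3094 to 1854, median centring 2831 to 1687 and normexp 2080 to 3431; 3243 passed without CBPKO sip300 replicate 1, and 3425 within the slide. The number of lists called for the difference was 11, of which 0 held with an estimated correlation (lowest adjusted p = 0.0546).

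Knockdown of p300 in wild-type cells moved fewer genes, which are ranked here among those well above background on at least 1 array of each group. FGF1, a fibroblast growth factor gene (3.59-fold higher, 1.84 ± 0.068), CALHM4, a channel gene (2.29 ± 0.27), the endothelin gene EDN2 (1.66 ± 0.23) and ZNF699 (1.62 ± 0.16) rose, as did PLEKHH2, well above background on 1 array of a group (1.65 ± 0.21). KRTAP2-3 (3.53 ± 0.11), CYP4F29P (2.02 ± 0.34) and ANKRD20A11P (1.86 ± 0.19) rose too but have near-identical relatives, and CYP4F29P lost its call without wild-type sip300 replicate 2 (1.83, adjusted p = 0.057). TMEM158 fell 5.96-fold (-2.58 ± 0.091), and with it fell cyclin D2 (CCND2, -2.29 ± 0.14), the adrenergic receptor gene ADRA1B (-2.14 ± 0.15), catalase (CAT, -1.98 ± 0.13), ATOH8 (-1.89 ± 0.18), the retinol carrier receptor gene STRA6 (-1.85 ± 0.21) and CYP27C1 (-1.76 ± 0.17). YAP and TEAD targets rose in 7 of 15 cases and fell in 1 (9 and 2 adjusted over the list alone, median 0.32, adjusted p = 4.58e-05, adjusted p = 0.0404 with an estimated correlation). Among these were CCN2 (1.5 ± 0.089), ANKRD1 (1.18 ± 0.13), LATS2 (0.72 ± 0.085) and CCN1 (0.62 ± 0.08). TGF-beta and SMAD targets fell in 10 of 15 cases and rose in 2, the same adjusted over the list alone (median -0.67, adjusted p = 0.000773, adjusted p = 0.0693 with an estimated correlation), with TGFBI (-1.39 ± 0.074) and ID2 (-0.80 ± 0.078) lower.

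Cell cycle genes showed little movement under sip300 in wild-type cells. Of 26 E2F and replication genes, 2 rose and 1 fell (adjusted p = 0.65), of 25 G2/M genes 2 fell (adjusted p = 0.158), and of 30 MYC targets 5 fell, 6 adjusted over the list alone (adjusted p = 0.0508); the first 2 counts were the same adjusted over the list alone. Camera also called EMT factors (1 higher to 2 lower of 11, 1 to 5 adjusted over the list alone, adjusted p = 0.0166, adjusted p = 0.581 with an estimated correlation), with TWIST2 (-0.95) and MMP14 (-0.97) lower. Further calls went to autophagy (2 to 1, 5 to 1 adjusted over the list alone, adjusted p = 0.0266, 0.0526 under quantile normalization) and cholesterol synthesis (1 to 4, 2 to 7 adjusted over the list alone, adjusted p = 0.0361, 0.133 after normexp). Histones (1 to 1, 1 to 7 adjusted over the list alone, adjusted p = 0.0361, 0.0528 after normexp) and ribosomal proteins (0 to 1, also adjusted over the list alone, adjusted p = 0.0266, 0.942 under quantile normalization) were called too. Each of these 4 stood at adjusted p = 0.634 with an estimated correlation. In all 2127 features passed limma's test, 1036 higher and 1091 lower, 221 by more than 2-fold. Quantile normalization split the calls 1276 higher to 956 lower and median centring 1103 to 812, so which side was larger is not settled. That count depended on single arrays and on the other groups: 885 passed without wild-type siNT replicate 1, 1343 without wild-type siNT replicate 2, 856 without wild-type sip300 replicate 1, 804 without wild-type sip300 replicate 2, 1281 with no filter on dim probes, 1072 within the slide and 506 with the 4 compared arrays alone.

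Knockdown of CBP in wild-type cells raised the splicing regulator PTBP2 5.45-fold (2.45 ± 0.076), EGR1 (2.28 ± 0.085), PLAC1 (1.95 ± 0.18), DCAF5 (1.81 ± 0.10), TMEM45A (1.80 ± 0.092) and NR4A3 (1.68 ± 0.15). TSPAN19, well above background on 1 array of a group (2.41 ± 0.42), and the pseudogene ZNF204P (1.84 ± 0.13) also rose. Falls were again ranked only among genes well above background on at least 1 array of each group. Within these, the drug efflux transporter gene ABCC3 fell 8.88-fold (-3.15 ± 0.20), followed by IGFBP3, a binding protein of insulin-like growth factors (-2.79 ± 0.16). SERTAD4 (-2.63 ± 0.098), LRRFIP1 (-2.54 ± 0.081), ARHGDIB (-2.48 ± 0.13) and ANKRD2 (-2.34 ± 0.21) came next. FAM25A (-2.54 ± 0.26), which has near-identical copies, and SLC22A4, well above background on 1 array of a group (-2.54 ± 0.26), fell as well. G2/M genes fell in 13 of 25 cases, 15 adjusted over the list alone (median -0.37, adjusted p = 2.31e-07, adjusted p = 0.331 with an estimated correlation). Among these were CENPA (-0.74 ± 0.075), CDC20 (-0.60 ± 0.066) and CCNB1 (-0.63 ± 0.085). E2F and replication genes split 1 to 9 of 26 (1 to 10 adjusted over the list alone, adjusted p = 0.00271, adjusted p = 0.388 with an estimated correlation), with MCM6 lower (-1.52 ± 0.073). Immediate early genes rose in 11 of 19 cases and fell in 2 (13 and 2 adjusted over the list alone, adjusted p = 8.35e-05, adjusted p = 0.331 with an estimated correlation). Among these were FOS (1.19 ± 0.14) and DUSP5 (0.73 ± 0.082). Genes of the ATF4 stress response rose in 8 of 20 cases and fell in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.000298, adjusted p = 0.331 with an estimated correlation). Among these were CHAC1 (1.39 ± 0.091), CTH (0.90 ± 0.094) and ASNS (0.77 ± 0.094).

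Further list changes under siCBP in wild-type cells covered cholesterol synthesis, where 8 of 23 genes fell and 0 rose (11 and 0 adjusted over the list alone, adjusted p = 0.000893, adjusted p = 0.388 with an estimated correlation). SREBF1 (-0.73) was among these. Autophagy genes split 7 to 1 of 20, also adjusted over the list alone (adjusted p = 0.0021, adjusted p = 0.388 with an estimated correlation), with NEU1 (1.05) and GABARAPL1 (0.72) higher. WNT targets split 1 to 4 of 10 (1 to 5 adjusted over the list alone, adjusted p = 0.016, adjusted p = 0.331 with an estimated correlation), with LEF1 lower (-0.82) and NKD2 higher (1.52). The list of HDACs and readers split 6 to 1 (7 to 1 adjusted over the list alone, adjusted p = 0.0114, 0.0651 after normexp). DNA repair genes split 0 to 4 (the same adjusted over the list alone, adjusted p = 0.0211) with RAD51C at -0.69, and epithelial markers split 0 to 4 (0 to 5 adjusted over the list alone, adjusted p = 0.0211) with KRT18 at -0.79. Each of these 3 stood at adjusted p = 0.388 with an estimated correlation. Ribosome biogenesis genes were higher in 3 of 20 cases, also adjusted over the list alone (adjusted p = 0.00196, adjusted p = 0.388 with an estimated correlation). Histones split 1 to 4 (1 to 7 adjusted over the list alone, adjusted p = 0.0211, adjusted p = 0.583 with an estimated correlation). In all 4391 features passed limma's test, 1822 higher and 2569 lower, 549 by more than 2-fold, and 3369 passed within the slide. The count was 2846 without wild-type siNT replicate 1, 2875 without wild-type siNT replicate 2, 2704 without wild-type siCBP replicate 1, 2822 without wild-type siCBP replicate 2, and 2004 with the 4 compared arrays alone.

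Both single knockdowns in wild-type cells were compared directly. CALHM4 (4.07 ± 0.27), IGFBP3 (3.64 ± 0.16), SERTAD4 (3.21 ± 0.098), KRTAP2-3 (3.14 ± 0.11) and ABCC3 (3.09 ± 0.20) were higher under sip300, and CCND2 (-2.37 ± 0.14), CAT (-2.25 ± 0.13), the osteopontin gene SPP1 (-2.22 ± 0.13), PTBP2 (-2.20 ± 0.076) and NR4A3 (-2.12 ± 0.15) higher under siCBP. MYC was lower under sip300 than under siCBP (-0.59 ± 0.067). YAP and TEAD targets were higher under sip300 in 9 of 15 cases, also adjusted over the list alone (median 0.54, adjusted p = 4.4e-05, adjusted p = 0.0421 with an estimated correlation), with ANKRD1 at 2.10 ± 0.13. Immediate early genes were lower under sip300 in 13 of 19 cases and higher in 1 (14 and 2 adjusted over the list alone, adjusted p = 4.4e-05, adjusted p = 0.174 with an estimated correlation), with EGR1 at -2.07 ± 0.085. ATF4 stress genes were lower in 10 of 20 cases and higher in 1 (11 and 1 adjusted over the list alone, adjusted p = 4.4e-05, adjusted p = 0.325 with an estimated correlation). G2/M genes were higher in 9 of 25 cases, 12 adjusted over the list alone (adjusted p = 4.4e-05, adjusted p = 0.394 with an estimated correlation). Camera called 5 lists higher and 4 lower under sip300, and 1 of these, the YAP and TEAD targets, held with an estimated correlation. In all 5010 features differed, 2753 higher and 2257 lower under sip300 (2363 and 3149 after normexp); 3900 differed within the slide and 3308 with the 4 compared arrays alone. The count was 3172 without wild-type sip300 replicate 1, 2787 without wild-type sip300 replicate 2, 3313 without wild-type siCBP replicate 1 and 3124 without wild-type siCBP replicate 2. The responses shared 345 higher and 446 lower calls, against 76.6 and 114 for independent lists. Because they share the siNT arrays, the correlation across genes of 0.299 is set beside 0.499 from 20 simulations with no effect, and the covariance of 0.0344 beside 0.0162, a difference of 0.0182. In those simulations 0 features were called in both, and with 2 control arrays that cannot be split, part of the excess in shared calls may still come from them.

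Whether the sip300 response depended on CBP status was tested as a difference of effects. EGR1 (4.82 ± 0.12), NR4A3 (4.38 ± 0.22), CCN2 (4.0 ± 0.13), CLIP3 (3.29 ± 0.13) and TM7SF2 (3.25 ± 0.14) had the larger rise in CBPKO cells. UCN2 (-5.61 ± 0.16), CCL2 (-5.21 ± 0.14), TGFBI (-4.46 ± 0.10) and DMBT1 (-3.93 ± 0.17) had the lower change there, as did KRTAP2-3 (-4.31 ± 0.16), which rose in wild-type cells. UCN2 and CCL2 started far higher in CBPKO than in wild-type cells under siNT (below). Their lower change therefore cannot be told apart from the unequal start. E2F and replication genes had the lower change in CBPKO cells in 25 of 26 cases (median difference -2.10, adjusted p = 2.06e-20, adjusted p = 0.0252 with an estimated correlation). Among these were CDC45 (-2.67 ± 0.09) and E2F1 (-2.20 ± 0.091). The lists of G2/M genes (24 of 25, 25 adjusted over the list alone, median -1.44), MYC targets (27 of 30, 28 adjusted over the list alone, median -0.93) and DNA repair (15 of 20, 16 adjusted over the list alone, median -1.34) did so too, each at adjusted p = 0.0443 with an estimated correlation. Interferon response genes had the higher change in 8 of 18 cases and the lower in 1, the same adjusted over the list alone (median 0.47, adjusted p = 0.00213, adjusted p = 0.0443 with an estimated correlation), as IRF9 (1.59 ± 0.19) did. Autophagy genes had the higher change in 14 of 20 cases, also adjusted over the list alone (median 0.67, adjusted p = 7.95e-08, adjusted p = 0.107 with an estimated correlation). Limma called 8473 differences, 3934 higher and 4539 lower, a balance that depended on the scaling: 4657 and 3732 under quantile normalization, 4210 and 3948 with median centring and 3527 and 5382 after normexp. Of the 15067 genes called in CBPKO cells, 8022 (53.2%) were called as moved further there than in wild-type cells, and 1581 were also called in wild-type cells in the same direction. The 15067 genes had a median absolute log2 change of 0.67 in CBPKO and 0.17 in wild-type cells. They were chosen by their call in CBPKO cells, so a larger change there is partly built in. Across all genes the responses correlated at r = 0.424.

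Whether the siCBP response depended on p300 status was tested in the same way. CCN2 (4.57 ± 0.13), TFPI2 (4.0 ± 0.20), TIMP1 (3.42 ± 0.11), NR4A3 (3.15 ± 0.22) and the filamin gene FLNC (2.96 ± 0.18) had the larger rise in p300KO cells. TMEM158 (-4.13 ± 0.13), SKA3 (-3.84 ± 0.17), PTX3 (-3.69 ± 0.15) and, with near-identical copies, H1-5 (-4.62 ± 0.39) and H3C15 (-4.03 ± 0.33) had the lower change. G2/M genes had the lower change in all 25 cases (median difference -2.44, adjusted p = 7.62e-28, adjusted p = 0.0218 with an estimated correlation). Among these were CDC20 (-2.49 ± 0.094) and CENPA (-2.75 ± 0.11). E2F and replication genes (25 of 26, median -1.89, adjusted p = 8.84e-25, adjusted p = 0.0146 with an estimated correlation) followed. MYC targets (22 of 30, 23 adjusted over the list alone, median -0.63) and DNA repair genes (13 of 20, median -1.43) did the same, each at adjusted p = 0.0374 with an estimated correlation. The autophagy list had the higher change in 15 of 20 cases, 16 adjusted over the list alone (median 0.67, adjusted p = 3.09e-09, adjusted p = 0.0962 with an estimated correlation). The counts of G2/M, E2F and DNA repair genes were the same adjusted over the list alone. The p53 target CDKN1A had a higher change of 1.83 ± 0.14. Limma called 6445 differences, 3278 higher and 3167 lower, against 2911 and 3125 after normexp and 2979 and 3147 with median centring. Of the 11167 genes called in p300KO cells, 5683 (50.9%) were called as moved further there, and 3104 were also called in wild-type cells in the same direction. The 11167 had a median absolute log2 change of 0.67 in p300KO and 0.22 in wild-type cells. They were chosen by their call in p300KO cells, so a larger change there is partly built in. Across all genes the responses correlated at r = 0.487.

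**Figure D4:**
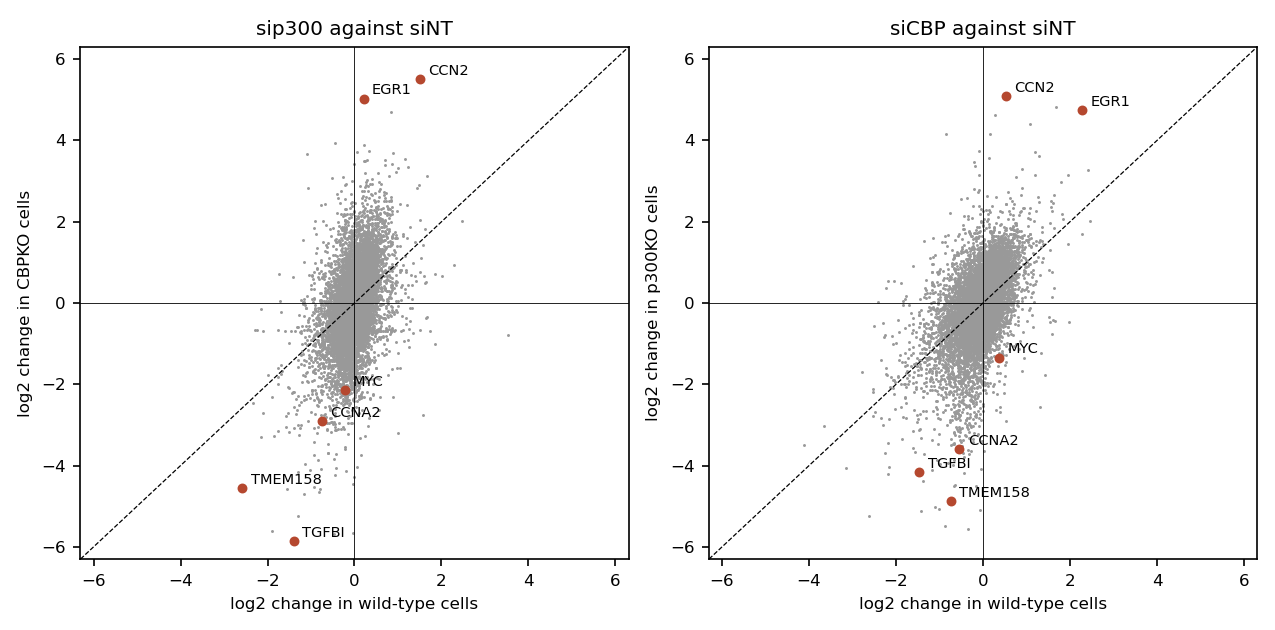
Log2 change in knockout cells (y axis) against that in wild-type cells (x axis) for each tested gene with a symbol, for sip300 (CBPKO) and siCBP (p300KO), with the dashed line at equal change and 6 genes marked. CCN2 lies at 5.51 in CBPKO against 1.5 in wild-type cells, and CCNA2 at -2.90 against -0.75.

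The untreated state of the knockout lines was compared under siNT. CBPKO cells had far more CD70, a ligand of the tumour necrosis factor family, than wild-type cells (38.4-fold, 5.26 ± 0.091), and more CCL2 (5.26 ± 0.099), GFPT2 (4.97 ± 0.11) and UCN2 (4.67 ± 0.12). They had less of the carbonic anhydrase gene CA2, well above background on 1 array of a group (-5.46 ± 0.16). ZDHHC11 (-4.95 ± 0.22) and RFPL4A (-5.19 ± 0.09), both with near-identical copies, were lower too. In p300KO cells CD70 (4.92 ± 0.091), PREX1 (4.79 ± 0.17), the kinase gene WNK2 (3.91 ± 0.22) and DPYSL5 (3.79 ± 0.14) were higher, and the arylsulfatase gene ARSA (-3.49 ± 0.12), BASP1 (-3.12 ± 0.14), STRA6 (-2.81 ± 0.21), PTN (-2.66 ± 0.19) and IGFBP3 (-2.51 ± 0.16) lower. CREBBP was higher there by 0.34 ± 0.088, a call lost without wild-type siNT replicate 2 (0.24) and without p300KO siNT replicate 2 (0.3). Cholesterol synthesis genes were lower in p300KO than in wild-type cells in 20 of 23 cases and higher in 1 (median -0.57, adjusted p = 1.11e-08, adjusted p = 0.194 with an estimated correlation). Among these were HMGCS1 (-1.07) and INSIG1 (-1.15). DNA repair genes were lower in 12 of 20 cases (adjusted p = 8.93e-06, adjusted p = 0.194 with an estimated correlation). Among these were ATM (-0.95) and FANCA (-1.15). TGF-beta targets were lower in 10 of 15 cases and higher in 3 (adjusted p = 0.00276, adjusted p = 0.194 with an estimated correlation), with TGFBI (-1.95); adjusted over the list alone, these 3 counts did not change. For p300KO against wild-type cells camera called 5 lists, each lower, and 0 of these held with an estimated correlation. For CBPKO against wild-type cells the number of lists called was 0 by camera (lowest adjusted p = 0.109). Limma called 15255 features for CBPKO against wild-type cells (8004 higher, 7251 lower, or 7219 and 7783 with median centring) and 10835 for p300KO (5870 higher, 4965 lower, or 4890 and 6304 with median centring and 5557 and 5698 under quantile normalization, and 6997 in all without p300KO siNT replicate 2). Wild-type arrays lay on one slide and knockout arrays on the other, so slide and line cannot be told apart in either.

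The knockout lines shared a slide and could be compared with each other, though each filled its own slide row. The calcium-binding protein gene CALB2 (5.69 ± 0.23), GALNT14 (5.45 ± 0.17), BASP1 (5.08 ± 0.14), ANXA3 (4.92 ± 0.084) and KHDRBS3 (4.77 ± 0.14) were higher in CBPKO cells, and VSTM1 (-5.57 ± 0.10), FSTL1 (-5.01 ± 0.10) and the apolipoprotein gene APOE (-4.99 ± 0.093) higher in p300KO cells. MYC was higher in CBPKO cells by 0.64 ± 0.067. E2F and replication genes were higher in CBPKO cells in 20 of 26 cases and lower in 2 (21 and 2 adjusted over the list alone, adjusted p = 1.05e-05, adjusted p = 0.233 with an estimated correlation). Among these were PCNA (1.26). ATF4 stress genes were higher in 15 of 20 cases, 16 adjusted over the list alone (adjusted p = 1.28e-05, adjusted p = 0.233 with an estimated correlation). Among these were PHGDH (1.15). Interferon response genes were lower in 12 of 18 cases and higher in 1, also adjusted over the list alone (median -0.64, adjusted p = 0.000157, adjusted p = 0.0685 with an estimated correlation). Among these were ISG15 (-3.58 ± 0.091). Camera called 5 lists higher and 1 lower in CBPKO cells, and 0 of these held with an estimated correlation. Limma called 10425 features, 4835 higher and 5590 lower in CBPKO cells, a difference that was gone under quantile normalization (5421 and 5412); 9354 passed within the slide and 6942 with the 4 compared arrays alone.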

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

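The tests of knockdown strength and the no-change simulations in this part were chosen after the results were seen; the tests on genes lowered in both lines were set out before their values were. The sip300 effect differed between CBPKO and wild-type cells for 8473 features, the siCBP effect differed between p300KO and wild-type cells for 6445, and the responses of both knockout lines differed from each other for 4889, each by limma's test of the difference.

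For sip300, the difference between lines (CBPKO minus wild-type, log2 ± SE) was 4.82 ± 0.12 for EGR1, 4.38 ± 0.22 for NR4A3, 4.0 ± 0.13 for CCN2, 3.29 ± 0.13 for CLIP3, 3.25 ± 0.14 for TM7SF2 and 1.08 ± 0.12 for CREBBP. It was -5.61 ± 0.16 for UCN2, -5.21 ± 0.14 for CCL2, -4.46 ± 0.10 for TGFBI, -4.31 ± 0.16 for KRTAP2-3, -3.93 ± 0.17 for DMBT1 and -1.91 ± 0.095 for MYC. The list medians of the same difference were -2.10 for E2F and DNA replication, -1.44 for G2/M and mitosis, -1.34 for DNA repair, -0.93 for MYC targets and 0.47 for the interferon response.

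For siCBP, the difference (p300KO minus wild-type) was 4.57 ± 0.13 for CCN2, 4.0 ± 0.20 for TFPI2, 3.42 ± 0.11 for TIMP1, 3.15 ± 0.22 for NR4A3 and 2.96 ± 0.18 for FLNC. It was -4.62 ± 0.39 for H1-5, -4.13 ± 0.13 for TMEM158, -4.03 ± 0.33 for H3C15, -3.84 ± 0.17 for SKA3, -3.69 ± 0.15 for PTX3 and -1.71 ± 0.095 for MYC. The list medians were -2.44 for G2/M and mitosis, -1.89 for E2F and DNA replication, -1.43 for DNA repair and -0.63 for MYC targets.

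Between the responses of both knockout lines (CBPKO with sip300 minus p300KO with siCBP), the difference was 4.03 ± 0.17 for SLC2A3, 2.87 ± 0.11 for GNE, 2.79 ± 0.41 for SRSF12, 2.79 ± 0.15 for PTX3, 2.73 ± 0.11 for TMCO1 and 2.39 ± 0.12 for CREBBP. It was -3.26 ± 0.18 for PXK, -3.21 ± 0.098 for TM4SF1, -3.10 ± 0.32 for CALB2, -2.94 ± 0.15 for GFPT2, -2.93 ± 0.19 for UTP15, -2.40 ± 0.27 for EP300 (from signals not well above background in 3 of the 4 groups, so no measured size) and -0.80 ± 0.095 for MYC.

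The larger response in the knockout lines may reflect the lack of the partner protein, or the siRNAs' sequence, or a weaker knockdown in wild-type cells. The siRNAs' sequence was not tested for the response as a whole, and that explanation stays open. For siCBP, the CREBBP level left in wild-type cells was -0.0891 (log2, wild-type minus p300KO). Its standard error, from the arrays of these groups alone, was 0.064. That argues against more CREBBP RNA left in wild-type cells. The fall itself was 1.24 in wild-type and 1.5 in p300KO cells (limma's difference -0.25 ± 0.12, adjusted p = 0.17), so a smaller fold knockdown stays open. For sip300, the EP300 level left was -0.74 in wild-type minus CBPKO cells (standard error 0.32, also from the arrays of these groups alone). The probe was not well above background in either group, so a difference in knockdown cannot be told apart from none. Other differences between the lines, such as clonal history or growth rate, stay open beside the lack of the partner.

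Of the genes tested, 68 fell by more than 2-fold under sip300 in both wild-type and CBPKO cells, a set that may follow loss of p300 or the sequence of the siRNA. Their median difference in p300KO against wild-type cells was -0.55 (-0.54 for the 67 without EP300 itself), with 42 called lower, 2 called higher and the rest not called. The spread over genes gave that median an error of 0.10, which treats genes as independent and holds no error between arrays. The set was chosen with the same siNT arrays, which alone gave a median of -0.0286 in 20 simulations without a difference; since line and slide cannot be told apart there, loss of p300 stays open. For the 26 not called lower, the median change under siCBP in p300KO cells was -0.86 (error 0.29, taken the same way over genes). In simulations without a change it was -0.0195. Of the 26, 18 were called lower. A median this low, rather than that count, was the outcome set beforehand as going against a sip300 sequence effect. All 26 were chosen for falling under sip300 in CBPKO cells, a response that correlated at r = 0.693 with this one across all genes. The simulations leave that shared response out, so the test cannot decide, and a sequence effect stays open for this set. The remaining 8 (CAT, GPKOW, RRAS2, UTP15, B4GALT6, CHD5, TRAPPC2 and FZD6) were singled out after their values were seen, and for these a sequence effect of sip300 stays open; CHD5 was also lower under siCBP in wild-type cells (-1.0, adjusted p = 0.00193), against the same siNT arrays, but not called in p300KO cells (-0.19, adjusted p = 0.351).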

How the results depend on the processing

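The alternative that centres arrays on their median was chosen after seeing the data. Of 117 counts of called features under alternatives other than leaving out an array, 6 moved by more than 1.5 times. Without a filter on dim probes, sip300 in wild-type cells called 1281 of 35257 tested. With only the arrays of the compared groups, which leaves fewer samples for the spread, sip300 in wild-type cells called 506, siCBP in wild-type cells 2004, sip300 against siCBP 3308 and CBPKO against p300KO cells 6942; within the slide, sip300 in wild-type cells called 1072. With 1 array left out (the lone array is assumed to vary like the other groups), 14 of 56 counts moved that far, and the ranges were 804 to 1343 for sip300 in wild-type cells, 2704 to 2875 for siCBP in wild-type cells, 2787 to 3313 for sip300 against siCBP, 3243 to 6346 for the difference of both knockout responses and 6997 to 8985 for p300KO against wild-type cells. For sip300 in CBPKO cells the count ran from 12509 to 18719 over the other alternatives and from 11910 to 14932 with an array left out, and for siCBP in p300KO cells from 9364 to 11368 and from 8992 to 9996.

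OVOL2 reversed for sip300 in CBPKO cells after normexp (-0.20, against 1.08, dim in both groups). Under quantile normalization RPL3 (0.0105, against -0.39) and RPL23 (0.0415, against -0.36) reversed there, with the ribosomal protein list (0.0324, against -0.36, camera adjusted p = 0.616). H2BC21 for siCBP in wild-type cells reversed with the mean of its probes (0.026, against -0.62). The cause was not tested. For lists, a reversal was judged by camera's direction, so a list median can change sign without being counted here. Of 955 named gene results, calls lost came to 266 over all fits with an array left out, 93 with the compared arrays alone, 41 within the slide, 33 without the filter, 32 after normexp, 15 under quantile normalization and 14 with the mean of probes. Of 330 list results, 81 lost their call with an estimated correlation. The overlap of both knockout responses kept r between 0.588 and 0.749 and 6457 to 8378 shared calls.

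The replicate numbers were checked for pairing: deviations of same-numbered arrays correlated at -0.16 to 0.26 over 21 group pairs, 8 of them over 0.1, so the numbers were not taken to pair arrays across groups. The 3 pairs among wild-type groups lay at 0.263, 0.119 and 0.211; there the number goes with the slide row, and it may mark a shared row or experiment. With the replicate block the counts were 15192 for sip300 in CBPKO cells, 2231 and 4505 for sip300 and siCBP in wild-type cells, 11289 for siCBP in p300KO cells, 8695, 6608 and 5007 for the differences, 5162 for sip300 against siCBP, and 15423, 10980 and 10548 for the lines under siNT. Signal over background limits the values of dim genes such as EP300.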

Other observations

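The tests of chromosome segments and of CBP function in this part were set out before their values were seen, and the test of the slide was chosen after. Beyond the comparisons above, part of the baseline differences between the lines ran in long stretches of neighbouring genes. The largest was a run of 325 consecutive tested genes from ZNF430 to ZC3H4, with a median of -0.91 in CBPKO against wild-type cells, of which 224 were called lower (68.9%); the same genes had a median of -0.24 in p300KO against wild-type cells and -0.05 under sip300 in CBPKO cells. Between the knockout lines, 223 genes from ZNF345 to KPTN had a median of -0.85 (155 called lower). Runs were picked by a shifted median in these same values, so a high share of calls in them is partly built in. Over all 24646 features, 7251 were called lower in CBPKO than in wild-type cells, and 5590 lower than in p300KO cells.

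A candidate explanation of the baseline differences is gain or loss of chromosome segments in the lines, with the slide and the loss of CBP function as others. The difference of a gene between CBPKO and p300KO cells correlated with the mean of 5 neighbours on each side at 0.281 across 14331 genes, against a highest value of 0.0288 in 100 shuffles of gene order and 0.0483 to 0.0949 for the 4 knockdowns, which is consistent with such segments for part of the differences; genes are not independent replicates. The slide as the whole cause is argued against by the 10425 features called between CBPKO and p300KO cells, which lay on one slide, though in separate rows of it. Over those genes, the difference correlated at 0.0934 with the siCBP effect in wild-type cells, too weak to show a part for loss of CBP function and, with its spread of 0.0098, too close to the bound of 0.1 set beforehand to exclude it. Arrays do not measure DNA copy number, so the segments remain a hypothesis.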
